A study of Homo sapiens with 2 samples.

How the data were processed

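Chromatin immunoprecipitation sequencing (ChIP-seq) with an antibody against AML1-ETO was analysed in Kasumi-1 cells carrying a scrambled control (SCR) or a short hairpin RNA against MEIS2 (KDMEIS2), with 1 library per condition. Per the labels' protocols, fixation took 10 minutes with 1% formaldehyde and the chromatin was sheared to between 200 and 700 bp, and a band of about 300 bp was cut from a gel before amplification. The submitters' processing notes name Trim Galore, Bowtie2 (version 2), HOMER (version 3.12) and the genome build hg19, and all coordinates are in hg19, counted from 1.

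Peaks were called per library with HOMER findPeaks, per the file headers, without an input or control library in the command. The headers give a peak size of 191 bp, a fragment length of 190 bp, at most 1 tag per position and a false discovery rate of 0.001. They also give a required fold of 10 over the surrounding 10000 bp with a Poisson p-value of 0.0001. Several kinds of value come with each peak. The deposited tag value of a peak is a signal, the tags in the peak per 10000000 tags of the library (normalized tags), per the file headers. The deposited findPeaks score is the number of position-limited tags in the peak. The deposited focus ratio is a fraction, and the deposited fold over the local region and its p-value compare the peak with its surroundings, per the file headers. These are the authors' values for a peak and were used to describe, rank or filter peaks and not to measure a change. A cut at the median of the SCR list was also applied to the KDMEIS2 list, as a setting. A second deposited table per library gives the signal of both libraries in the 400 bp around each peak of that library, again in normalized tags, with the nearest transcription start site (TSS), its gene and the location, per the file headers.

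With the library totals in the headers, 100% of the 400 bp values came out as whole tags within a tolerance of 0.02, so counts of tags could be recovered. The library totals were 8165717 tags for SCR and 12334377 for KDMEIS2, so that 1 tag was worth 1.22 and 0.811 normalized tags. A count of 0 allows up to 3 tags, or 3.67 normalized tags in SCR and 2.43 in KDMEIS2. The KDMEIS2/SCR ratio of a region was taken at these totals, with a 95% exact conditional binomial interval. Shares have exact Clopper-Pearson intervals and single tag values exact Poisson intervals. All of them cover counting error only.

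Peaks on the main chromosomes were used. A peak was shared if it overlapped a peak of the other list by at least 1 bp. The overlap was computed with a function written for this work in place of bedtools, which had been planned. The chance level came from 100 shuffles of the KDMEIS2 peaks within their chromosomes. Location and assigned gene were those in the deposited tables, and 99.7% of 7828 assigned Entrez identifiers were found in a RefSeq gene table of assembly GRCh38.p14, from which names and transcript identifiers alone were taken. For 9 gene lists written before the data were examined, the number of genes with an assigned peak was set against 10000 random lists of the same size from 19443 protein-coding genes. Lists matched on the distance to neighbouring genes had been planned and were not run, because no hg19 annotation was used here, and motif counts were not run for lack of an hg19 sequence. The AML1-ETO target list comes from background knowledge and not from these samples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated tags at 5074 regions with 200 regions raised 2-fold, the median ratio of the raised regions was 2.05 and that of the others 0.993, and 96.3% of the intervals held the true ratio. The simulation drew Poisson tags at fixed regions, without picking regions by their tags and without variation between libraries. It therefore checks the computation and not the coverage at picked peaks.

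The rule for named genes was also fixed beforehand. It takes MEIS2, YES1, RUNX1 and RUNX1T1, then the 10 highest peaks by the authors' tag value that were shared, in SCR only and in KDMEIS2 only. It adds the 10 regions with the largest and the smallest ratio among those with at least 20 tags in the higher library, and up to 4 members of each list. The rule did not say which list's tag value ranks a shared peak, and the mean over the 2 lists was settled on after seeing the data. Also chosen then were the naming of further peaks outside satellite and rRNA repeats, the full peak sets of single genes, the comparison without those repeats, the thinning of the KDMEIS2 tags to the SCR depth, with and without the local filter applied again, and the universe of protein-coding genes. So were the upper and lower 2.5% as the threshold for a list, the tag limits used to split the SCR-only peaks, and the 20 kb window. The other settings tried were stricter peak sets, other definitions of a shared peak, scaling by the median ratio at shared peaks, a wider promoter and peaks within 10000 bp of a TSS.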

Results

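AML1-ETO is the fusion of the blood transcription factor RUNX1 with the corepressor RUNX1T1, and Kasumi-1 is a human leukaemia cell line that carries the translocation producing it. MEIS2 is a homeodomain transcription factor of the TALE class. The series asked how lowering MEIS2 affects where AML1-ETO sits on DNA. It holds 1 SCR library and 1 KDMEIS2 library, with no replicates, so no difference has a replicate check and no test between conditions was made. Every comparison of reads below compares these 2 libraries, not the conditions. The SCR library had 8165717 tags and the KDMEIS2 library 12334377, 1.51 times as many. Expression of MEIS2 itself was not analysed here.

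AML1-ETO peaks were more numerous in the KDMEIS2 list, and most of the SCR peaks were found again in it. The KDMEIS2 list held 11078 peaks and the SCR list 5074, a ratio of 2.18. RUNX1 had 8 assigned peaks against 2 in SCR, or 7 against 3 when counted by its own transcripts and promoter. BCOR, a corepressor of BCL6, had 12 against 2, and SMAD7, an inhibitor of TGF-beta signalling, had 10 against 3. ST3GAL1, a sialyltransferase, had 12 against 7. Assigned peaks can lie far from their gene. The 2 SCR peaks of BCOR lay 237 and 242 kb from its start, and its KDMEIS2 peaks from 1.21 to 325 kb. For SMAD7 the distances ran from 25.1 to 110 kb in SCR and from 1.82 to 110 kb in KDMEIS2. BCOR, SMAD7 and ST3GAL1 were picked after their values were seen, as genes with the most KDMEIS2 peaks. At least 1 peak was assigned to 7137 genes in KDMEIS2 and to 3917 in SCR, and 3226 of the latter, 82.4%, had a peak in both lists.

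Of the SCR peaks, 3455 or 68.1% (95% interval 66.8 to 69.4%) overlapped a KDMEIS2 peak, against 0.156% on average after shuffling. The shared peaks made up 31.2% (30.3 to 32.1%) of the KDMEIS2 list, and 7623 KDMEIS2 peaks overlapped no SCR peak. Recovery rose with the SCR tags of a peak, from 27.4% (24.8 to 30.04%) at 9 to 10 tags to 94.9% (92.7 to 96.6%) at 25 to 40 tags, and was 93.6% (88.8 to 96.7%) above that. Taken at an equal number of 5074 peaks, the lists shared 55.1% of their peaks, and the KDMEIS2 peaks were assigned to 3700 genes, fewer than the 3917 of SCR. The number of peaks called moves with depth, and the KDMEIS2 library was the deeper one. Both the number and the sharing also depend on the required fold over the local region. That filter removed 57.2% of 25888 putative KDMEIS2 peaks and 30.5% of 7303 putative SCR peaks.

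At the peaks they shared, the KDMEIS2 library had more tags than SCR after normalization to library size. The median ratio was 1.92 (log2 0.94), and KDMEIS2 was higher at 3234 of the 3455 regions, 93.6%. Among the highest shared peaks outside satellite and rRNA repeats, the promoter of IGFBP7, which encodes a secreted growth factor-binding protein (chromosome 4, 57976957 to 57977147), had 220 normalized tags in KDMEIS2 and 107 in SCR. That is a ratio of 2.06 (95% counting interval 1.61 to 2.66). The ratio was 2.09 (1.64 to 2.69) at an intergenic peak near ADCY7, an adenylyl cyclase (chromosome 16, 50315995 to 50316185). It was 1.83 (1.44 to 2.34) at an intergenic peak nearest SFMBT2, a Polycomb group gene (chromosome 10, 7550105 to 7550295).

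Further peaks of this group, named after their values were seen, gave similar ratios. The peak beside TYROBP, a signalling adaptor of myeloid cells (chromosome 19, 36400271 to 36400461), had 58 SCR and 228 KDMEIS2 tags and a ratio of 2.60 (1.94 to 3.53). RPS6KA1, a ribosomal S6 kinase, had a ratio of 2.29 (1.76 to 2.997) in its intron, PREX1, an exchange factor for Rac, 2.16 (1.60 to 2.96), and CYP51A1, an enzyme of cholesterol synthesis, 1.48 (1.15 to 1.92). Some of the highest shared peaks had ratios near or below 1. An alpha satellite on chromosome 1 whose nearest gene is EMBP1 (121485113 to 121485303) had 758 SCR and 763 KDMEIS2 tags, a ratio of 0.666 (0.602 to 0.738). An rRNA repeat whose nearest gene is HFM1 had a ratio of 1.26 (1.04 to 1.53). The peak at MIR3687 had a ratio of 0.991 (0.850 to 1.16), and the promoter of the pseudogene ROCK1P1 0.988 (0.794 to 1.23). At the 79 shared peaks in satellite repeats the median ratio was 0.764, and KDMEIS2 was higher at 6 of them.

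**Figure D1:**
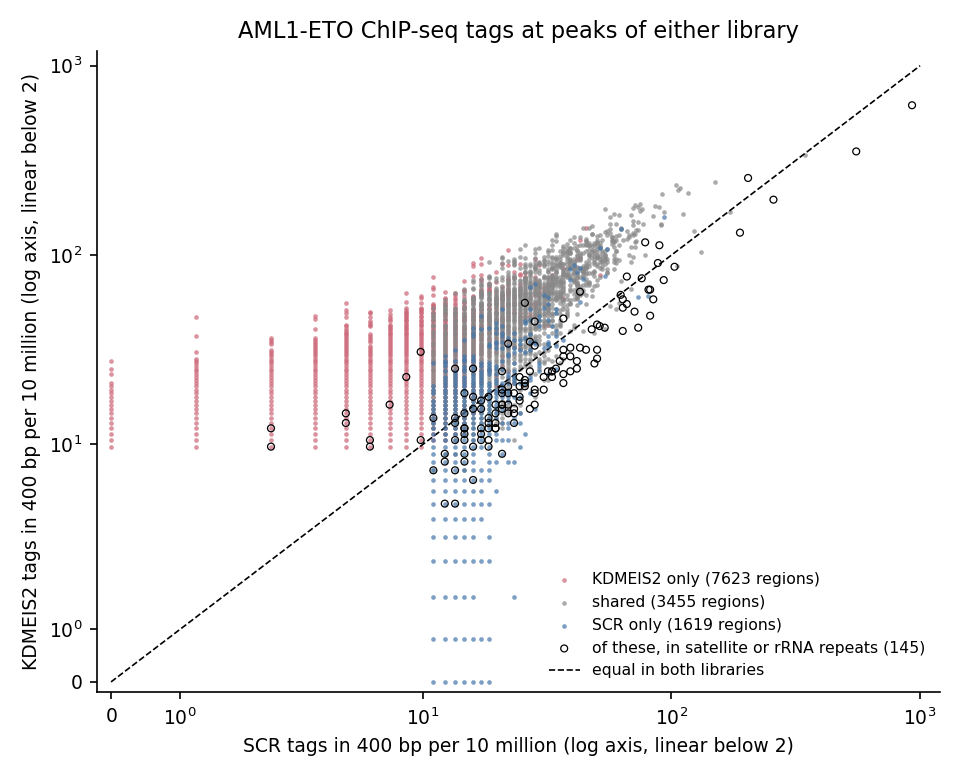
Tags in the 400 bp around each peak, per 10000000 tags of the library, for SCR (x axis) and KDMEIS2 (y axis), both on log axes that are linear below 2; a point can hold several regions, colours give the list a peak was found in and circles mark satellite or rRNA repeats. Most of the 3455 shared regions lie above the dashed line of equal tags, while 73 of the 79 shared satellite regions lie below it.

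Over all SCR peaks the median ratio was 1.56, with KDMEIS2 higher at 69.9% of them, and over all KDMEIS2 peaks it was 2.54. A region picked for a peak in 1 library has its tags in that library raised by the picking, so the first value lies low and the second high. Scaled instead by the median ratio at shared peaks, a shift of 1.92-fold, the SCR peaks had a median of 0.815, below 1, and the KDMEIS2 peaks one of 1.32. Under that scaling, every ratio below 1.92 given here for a region falls below 1. Among the 1224 SCR peaks with at least 20 SCR tags, KDMEIS2 was higher at 1110, or 90.7%.

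KIT, the receptor of stem cell factor and a marker of blood progenitors, had the highest peak found only in KDMEIS2. It lay in intron 1 (chromosome 4, 55554180 to 55554370) with 172 KDMEIS2 and 37 SCR tags, a ratio of 3.08 (2.15 to 4.52). An SCR-only peak of KIT was centred 339 bp away (55554519 to 55554709) and also had more KDMEIS2 tags, 170 against 51, a ratio of 2.21 (1.61 to 3.08). The calling kept peaks of 1 library at least 382 bp apart, so these 2 peaks could not both be called in 1 library. They may be 1 site with a different centre called in each library. Other high KDMEIS2-only peaks lay in introns of SEPT9, a septin of the cytoskeleton (ratio 2.30, 1.56 to 3.47), and of PPM1F, a protein phosphatase (2.38, 1.54 to 3.79). Another had NFATC3, a calcium-regulated transcription factor, as its nearest gene (4.82, 2.93 to 8.38). It lay 10.4 kb upstream of the NFATC3 start, in an intron of a different transcript. An intergenic peak nearest DCTD, a deaminase of nucleotide metabolism, had a ratio of 5.63 (3.23 to 10.6).

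Of the 8679 regions with at least 20 tags in the higher library, 34 had no SCR tag, so that their ratios have only a lower bound and cannot be ranked against those of regions with a few SCR tags. Against a floor of 3 tags in the SCR library, the tags near RBM38, an RNA-binding protein gene (chromosome 20, 55965102 to 55965292, 34 KDMEIS2 tags), were at least 7.503-fold higher in KDMEIS2. They were at least 6.84-fold higher near CEP68, a centrosome protein gene, and at least 5.52-fold higher at the promoter of TNFSF13, a cytokine of the tumour necrosis factor family. In the other direction, 2 of the 8679 regions had a ratio below 0.5, near B4GALT3, a galactosyltransferase gene (20 SCR and 12 KDMEIS2 tags, ratio 0.397, 0.177 to 0.853), and near KDELR3, an endoplasmic reticulum retention receptor gene (21 and 14 tags, 0.441, 0.208 to 0.910). Also among the 10 smallest ratios were the promoters of SNX16, a sorting nexin, and LSP1, a leukocyte actin-binding protein, at 0.547 (0.282 to 1.05) and 0.596 (0.297 to 1.19), with intervals that include 1. Satellite repeats were among them too. Those nearest SPIN4 (0.546, 0.334 to 0.888), POTEA (0.563, 0.380 to 0.831) and ANKRD26P1 (0.565, 0.349 to 0.910) had intervals below 1. Those nearest LOC286297 (0.572, 0.293 to 1.11) and LOC643955 (0.574, 0.326 to 1.004) did not. The limit of 20 tags hides low ratios at weak peaks, since 1224 of the 5074 SCR peaks had at least 20 SCR tags and the 1619 peaks found in SCR only had a median ratio of 0.441.

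Of the key genes fixed beforehand, RUNX1 carried AML1-ETO peaks and the others had none assigned. No peak of either list was assigned to MEIS2, to YES1, a SRC family kinase, or to RUNX1T1, or lay inside them. At RUNX1 all 8 KDMEIS2 peaks had more tags in KDMEIS2, with ratios from 1.52 to 5.96, as did 97.7% of all KDMEIS2 peaks, which were picked for their KDMEIS2 tags. The peak at the RUNX1 promoter (chromosome 21, 36421427 to 36421617) had 115 KDMEIS2 and 50 SCR tags, a ratio of 1.52 (1.08 to 2.17), which falls to 0.793 under scaling by the shared peaks. A peak in the 5' UTR at an inner start site (36260336 to 36260526) was called in KDMEIS2 only and had 98 and 20 tags, a ratio of 3.24 (1.99 to 5.54). An intronic peak (36283731 to 36283921) had 63 and 7 tags and a ratio of 5.96 (2.73 to 15.4). Because Kasumi-1 carries RUNX1 sequence in the fusion as well as in the intact gene, the tags do not say which copy they come from.

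**Figure D2:**
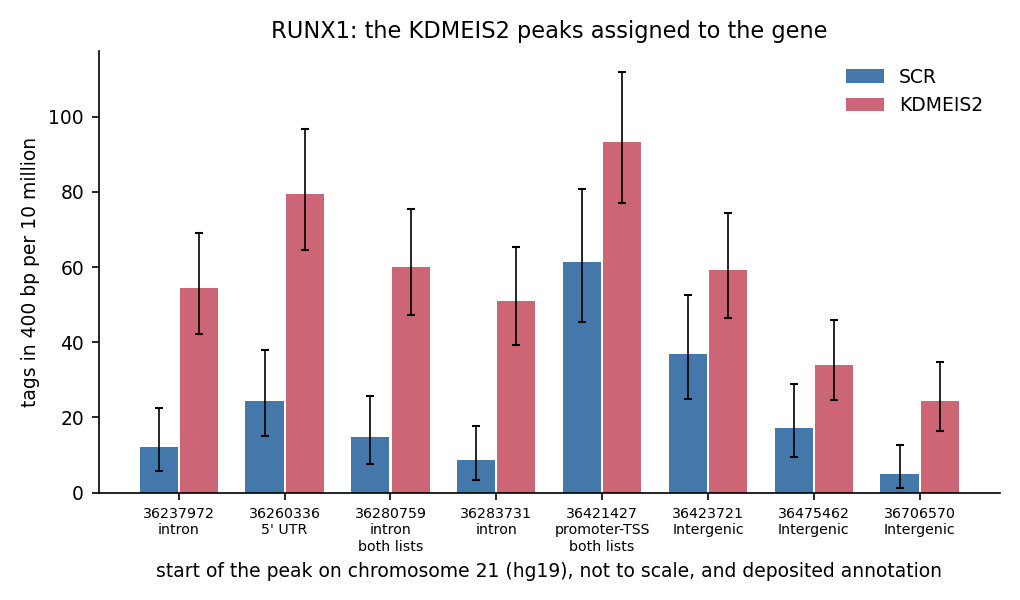
Tags in 400 bp, per 10000000 tags of the library, at the 8 KDMEIS2 peaks assigned to RUNX1, in order along chromosome 21 (hg19); bars are the SCR and KDMEIS2 libraries and error bars are 95% Poisson intervals that cover counting error only. KDMEIS2 is higher at each peak, with the smallest ratio, 1.52, at the promoter.

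Known AML1-ETO targets were the gene group most often marked by a peak, already in SCR. Of 25 target genes, 18 had an SCR peak and 19 a KDMEIS2 peak, where random lists had a median of 4 and 8 (percentile 100 in both lists). Unless an SCR peak is named, the ratios of listed genes here and below are at KDMEIS2 peaks. These peaks were picked for their KDMEIS2 tags, and 97.7% of all KDMEIS2 peaks were higher in KDMEIS2. Ratios above 1 at them therefore do not set the listed genes apart. Besides RUNX1, given above, the genes of this list with the highest peaks were RUNX3, a RUNX1 relative (ratio 2.83, 2.05 to 3.98), NFE2, a transcription factor of erythroid and megakaryocytic cells (1.75, 1.34 to 2.29), and RASSF2, a tumour suppressor (3.57, 2.14 to 6.27). The RUNX3 peak lay between genes, 69.1 kb from the RUNX3 start. SPI1, the master regulator of myeloid cells, had 1 SCR peak in its transcripts that was assigned to another gene, and a KDMEIS2 peak at its promoter with 31 against 3 tags (ratio 6.84, 2.13 to 35.0). CDKN1A, the p21 cell cycle inhibitor, had a peak in SCR alone, with 12 SCR and 9 KDMEIS2 tags (0.497, 0.185 to 1.28).

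Regulators of stem and progenitor cells were also marked more often than random lists, 11 of 27 in SCR (percentile 99.8) and 16 in KDMEIS2 (99.8). Besides KIT, the examples were LMO2, a bridging factor of blood stem cells (ratio 2.07, 1.44 to 3.01), IKZF1, a lymphoid transcription factor (2.12, 1.43 to 3.22), and CBFA2T3, a relative of RUNX1T1 (2.79, 1.89 to 4.25). The IKZF1 and CBFA2T3 peaks lay between genes, 91.3 and 55.1 kb from the starts of these genes, the latter in a LINE repeat. CBFA2T3 had 6 KDMEIS2 and 3 SCR peaks, of which 3 and 2 lay within 10000 bp of its start. Among myeloid differentiation genes, 9 of 28 had an SCR peak (percentile 97.4, under the threshold) and 16 a KDMEIS2 peak (99.7). The promoter of MPO, the neutrophil myeloperoxidase, had 94 KDMEIS2 and 19 SCR tags (3.28, 1.99 to 5.68). The SCR peak of MPO, 4.01 kb from its start, had 55 and 21 (1.73, 1.03 to 3.02), or 0.903 under scaling by the shared peaks. The promoter of CTSG, a neutrophil protease, had 73 and 29 (1.67, 1.07 to 2.66), and that of ANPEP, the surface marker CD13, 95 and 42 (1.497, 1.03 to 2.21). A peak 29.5 kb from the start of IRF8, a regulator of monocytes, had a ratio of 1.83 (1.28 to 2.66). The last 3 ratios fall below 1 under scaling by the shared peaks.

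SRC family kinases and their adaptors had a peak at 8 of 18 genes in SCR (percentile 99.7) and at 11 in KDMEIS2 (99.5). SRC itself had an intronic KDMEIS2 peak with 92 against 14 tags (4.35, 2.47 to 8.27), PAG1, an adaptor that binds CSK, had 116 against 17 (4.52, 2.70 to 8.02), and LYN, a kinase of myeloid and B cells, 74 against 23 (2.13, 1.32 to 3.56). HOX and TALE genes, which pattern the embryo and recur in leukaemia, were marked less often than random lists, at 1 of 30 genes in SCR (percentile 1.57) and 2 in KDMEIS2 (0.06). Most of them stand side by side in HOX clusters, which the random lists do not match, so these percentiles are a loose guide. TGIF1 was marked in both lists, by a peak about 45.9 kb from its start, with 35 KDMEIS2 and 12 SCR tags (1.93, 0.979 to 4.09).

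For the markers of other cell types, erythroid and megakaryocytic genes had a peak at 2 of 22 genes in SCR (percentile 17.6) and 5 in KDMEIS2 (19.6), and genes of non-blood tissues at 4 and 6 of 28 (37.9 and 13.3). B and T lymphoid genes had one at 7 of 27 in SCR (88.4) and 14 in KDMEIS2 (98.6), among them CD2, a T cell adhesion molecule, with 70 against 12 tags (3.86, 2.08 to 7.83). Cell cycle and apoptosis genes had one at 7 and 10 of 25 (91.9 and 81.5), with CCND3, a G1 cyclin, at 157 against 54 tags (1.92, 1.40 to 2.67). CCND2, CDKN1A, LCK, MPO and NFE2 each stand in 2 lists. Each percentile describes 1 library, and the difference between libraries was not tested. With peaks within 10000 bp of a TSS alone, the SRC family list left the upper 2.5% in both libraries, at 96.3 and 93.995, and the myeloid and lymphoid lists left it in KDMEIS2, at 96.2 and 93.0. The HOX and TALE list left the lower 2.5% in SCR, at 3.36.

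**Figure D3:**
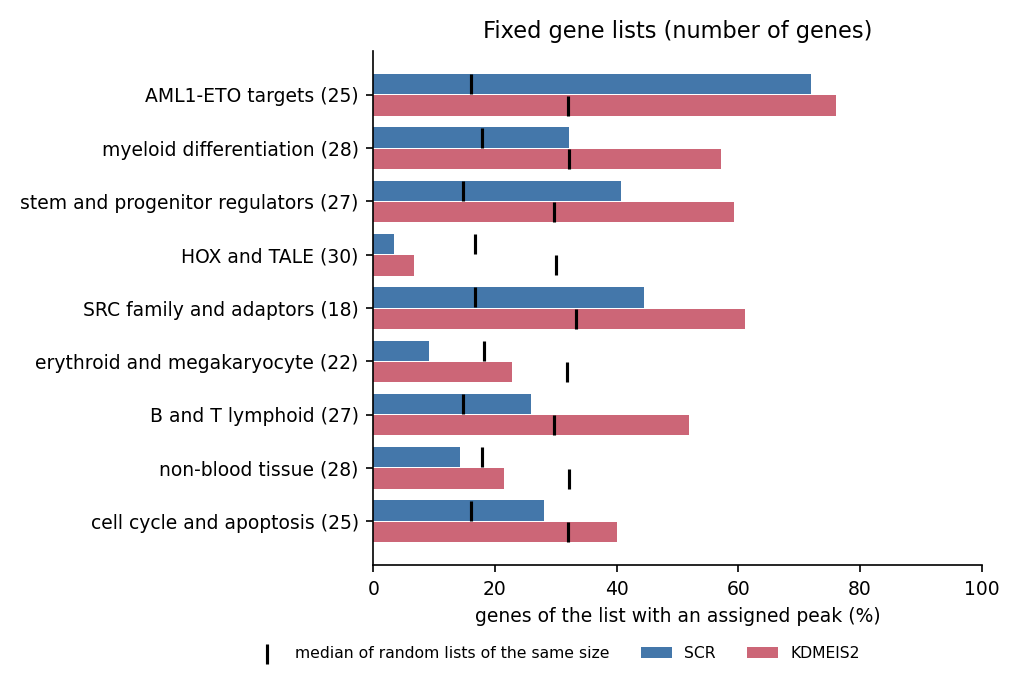
Share of the genes of each list that have an assigned peak in the SCR and KDMEIS2 lists (x axis, percent), with the number of genes in brackets; black marks are the median of 10000 random lists of the same size. The AML1-ETO targets stand at 72% and 76%, and the HOX and TALE genes below their random medians in both libraries.

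The 1619 peaks found in SCR only were mostly weak, and many of their regions still held KDMEIS2 tags. Of them, 1219 or 75.3% had at most 12 SCR tags, and 166 or 10.3% lay within 1000 bp of a KDMEIS2 peak that they did not overlap. A KDMEIS2/SCR ratio of at least 1 was found at 314 or 19.4%. Examples of this last group were KIT, ZFP36L2, an RNA-decay factor (ratio 1.96, 1.39 to 2.81), and FURIN, a proprotein convertase (1.44, 1.00 to 2.11). The nearest KDMEIS2 peak was centred 339 bp away for KIT and 233 bp away for FURIN. At the other end, 582 peaks had at most 3 KDMEIS2 tags, where the tag density in the header gives 2.47 per 400 bp. Among listed genes with a peak in SCR alone, MECOM, a stem cell transcription factor, had 12 SCR tags and 1 KDMEIS2 tag in an intron (0.0552, 0.00129 to 0.373), and FRK, a SRC-related kinase, had 15 and 3 (0.132, 0.0246 to 0.468). The promoter of CEBPD, a myeloid transcription factor, had 13 and 25 (1.27, 0.627 to 2.71), a ratio that falls below 1 under scaling by the shared peaks.

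These SCR-only peaks differed in place with their KDMEIS2 tags. Of the 582 peaks with at most 3 KDMEIS2 tags, 3.78% (2.38 to 5.67%) lay within 1000 bp of a TSS and 18.7% (15.6 to 22.1%) in SINE repeats. Of the 308 with 16 to 30 tags, 40.6% (35.1 to 46.3%) lay near a TSS and 0.649% (0.0787 to 2.33%) in SINE repeats. The share near a TSS did not keep rising with the tags, and was 26.6% (19.1 to 35.1%) for the 128 peaks with 31 to 196 KDMEIS2 tags, of which 3.91% (1.28 to 8.88%) lay in SINE repeats. Among weak shared peaks, those with at most 12 SCR tags, the shares were 20.7% (18.1 to 23.5%) and 2.04% (1.21 to 3.20%).

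**Figure D4:**
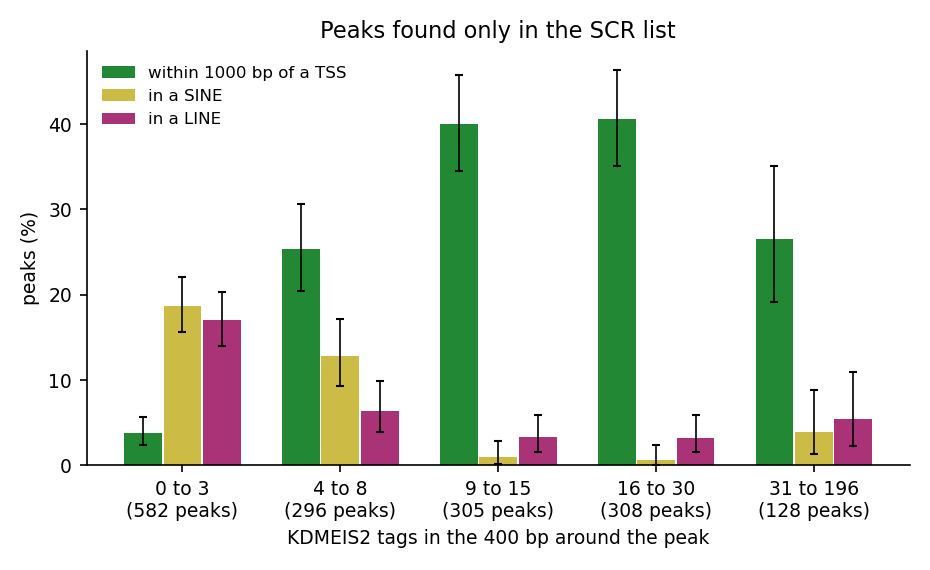
Peaks found only in SCR, split by the KDMEIS2 tags in the surrounding 400 bp (x axis), with the share within 1000 bp of a TSS, in SINE and in LINE repeats (y axis, percent); error bars are 95% exact binomial intervals. The share near a TSS is 3.78% at 0 to 3 KDMEIS2 tags, 40.6% at 16 to 30 and 26.6% at 31 to 196.

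AML1-ETO peaks lay mainly in introns and between genes in both lists. Introns held 39.7% (38.4 to 41.1%) of SCR and 39.6% (38.7 to 40.5%) of KDMEIS2 peaks, and intergenic sequence 39.1% (37.8 to 40.5%) and 38.2% (37.3 to 39.1%). Within 1000 bp of a TSS lay 19.7% (18.7 to 20.9%) of SCR and 20.6% (19.9 to 21.4%) of KDMEIS2 peaks. The median distance to a TSS was 17.9 kb in both. Some repeat classes took different shares, with SINE repeats at 4.43% (3.88 to 5.04%) of SCR and 2.68% (2.39 to 2.999%) of KDMEIS2 peaks and satellite repeats at 2.17% (1.79 to 2.61%) and 0.876% (0.711 to 1.07%). In numbers these were 225 and 297 SINE and 110 and 97 satellite peaks. Of the 225 SCR peaks in SINE repeats, 109 were among the 582 SCR-only peaks with at most 3 KDMEIS2 tags. The higher SINE share of SCR therefore rests largely on that set. The intervals overlapped for LINE repeats, at 6.37% (5.71 to 7.07%) and 6.19% (5.75 to 6.66%), and for LTR repeats, at 6.33% (5.67 to 7.03%) and 7.25% (6.77 to 7.75%). At shared peaks outside satellite and rRNA repeats, the median KDMEIS2/SCR ratio was 1.84 at promoters, 1.99 in introns and 1.91 between genes.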

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

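The mitochondrial chromosome carried 1 peak in the SCR list and none in the KDMEIS2 list, and it was left out of every comparison above. It was picked out because it is a signal outside the data compared, above what a count of 0 allows. The peak (positions 100 to 290) had 835 tags per 10000000 in the SCR library and 711 in the KDMEIS2 library. From 682 and 877 tags the KDMEIS2/SCR ratio was 0.851 (0.769 to 0.942, counting error only), below 1 where the median of the shared nuclear peaks was 1.92. No biological explanation was tested.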

How the results depend on the processing

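No paired analysis was possible because each condition has 1 library and no test was made. The settings without satellite and rRNA repeats and thinned to the SCR depth, with or without the local filter applied again, were chosen after seeing the data. The KDMEIS2 list was the longer one under each setting of the peak number. A cut at the median SCR tag value left 2867 SCR peaks. The shared part of the SCR and KDMEIS2 lists was 61.2% and 28.0% with 50% reciprocal overlap, 62.1% and 28.4% with centres within 100 bp, 71.4% and 32.9% within 1000 bp, 55.1% and 55.1% at equal numbers, and 81.4% and 37.3% in the top 50% of each list. Scaling by the shared peaks reversed the median ratio at SCR peaks to 0.815, by construction, and lowered that at KDMEIS2 peaks to 1.32. Restriction to shared peaks gave 1.92 and 1.93, and SCR peaks without satellite and rRNA repeats 1.59. Within 5000 bp of a TSS lay 29.3% and 29.4% of peaks, and 18.7% of the top 50% of KDMEIS2 peaks lay within 1000 bp. Genes with a peak within 10000 bp numbered 1859 in SCR and 3894 in KDMEIS2, and at equal numbers of peaks 3700 in KDMEIS2, below the 3917 of SCR. With peaks within 10000 bp, the percentile was 3.36 for HOX and TALE in SCR, 96.3 and 93.995 for the SRC family in SCR and KDMEIS2, and, in KDMEIS2, 96.2 for myeloid, 93.0 for lymphoid and 1.53 for non-blood genes, the last now in the lower 2.5%. The cause of these list changes was not tested. The other 30 percentiles of lists kept their side of the threshold, and 7 of 8 peak numbers stayed within 1.5 times. Matched random lists and the motif counts with their alternatives were not run. With 9 tags as the SCR calling threshold, the depth limits what can be said of weak regions.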

Other observations

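Some repeat families and single genes had more AML1-ETO peaks in KDMEIS2, as the whole lists did. LTR12C elements, long terminal repeats of an endogenous retrovirus, held 41 KDMEIS2 and 13 SCR peaks, a ratio of 3.15, and LTR33 elements 33 and 10, a ratio of 3.30. The KDMEIS2 peaks in these families had median tag ratios of 2.72 and 2.48. Over all peaks the ratio of peak numbers was 2.18 and the median tag ratio at KDMEIS2 peaks 2.54, and with so few SCR peaks per family no family was shown to differ from these. SORL1, a sorting receptor, had 11 KDMEIS2 and 4 SCR peaks, and SMAD3, a mediator of TGF-beta signalling, 9 and 3. CD83, a marker of mature dendritic cells, also had 9 and 3, while LGMN, a lysosomal protease, had 8 and 9. These genes and families were named after their values were seen.

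The tags of whole gene lists were compared in a way chosen after seeing the data. Among KDMEIS2 peaks outside satellite and rRNA repeats, the 26 peaks of the SRC family list had a median KDMEIS2/SCR ratio of 3.12, at percentile 99.2 of 10000 random sets of peaks matched on tags. The 6 peaks of erythroid and megakaryocytic genes had 1.70, at percentile 2.11, and under scaling by the shared peaks 0.886. The other 7 lists stood between percentiles 32.2 and 77.9, with medians from 2.35 to 2.95. With 9 lists looked at, an extreme percentile by chance is not excluded. YES1 had no peak and added nothing to this median.

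The fall of tags at satellite peaks in KDMEIS2 was larger than the room taken by its called peaks. Tags outside the called peaks were not split into enriched and background tags, so the room taken by all enriched sites is not known. Per the file headers, tags outside peaks made up 99.1% of the SCR and 97.5% of the KDMEIS2 library, while the median ratio in satellite repeats was 0.736 at the 110 SCR peaks, 0.764 at the 79 shared peaks and 0.794 at the 97 KDMEIS2 peaks, of which 18 were higher in KDMEIS2. The first set was picked for SCR tags and the last for KDMEIS2 tags.

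Of the tests in the next 2 paragraphs, those of a scaling error, of immunoprecipitation efficiency and of independent random placement were chosen after the result was seen, as were the thinning settings among the alternatives. The first pattern is that the KDMEIS2 library had more peaks and more tags per peak. Deeper sequencing is argued against as the whole cause, since after random thinning to the SCR depth 10036 KDMEIS2 peaks on average still held the 9 tags of the SCR threshold, 1.98 times the 5074 SCR peaks. That count did not apply the local filter again. With the filter applied to the thinned tags, from local tags derived from the deposited folds, 9433 peaks on average were left, 1.86 times the SCR number. An error in the library totals would move every region alike, and the median ratio was 0.764 at shared satellite peaks against 1.94 at shared peaks outside satellite and rRNA repeats. A more efficient immunoprecipitation may be the cause. The headers put 0.86% of SCR and 2.5% of KDMEIS2 tags in peaks. That share is counted in the called peaks, so it restates the pattern and would also rise with wider binding. Among location classes of at least 50 shared peaks outside satellite and rRNA repeats, the highest median ratio was 1.08 times the lowest, as 1 factor for these places would give. A change of binding spread evenly over these classes would give the same. Neither the share nor the comparison of classes can therefore decide between the 2. The 34 shared peaks in 3' UTRs, at 2.16, were too few for this comparison. The satellite peaks do not follow that factor, nor do the peaks at MIR3687 and ROCK1P1, at 0.991 and 0.988. Without an input library, bound regions cannot be told from background there, so these ratios do not argue against a more efficient immunoprecipitation. With 1 library per condition, a more efficient immunoprecipitation cannot be told apart from a wider binding of AML1-ETO after MEIS2 knockdown, which stays open as a hypothesis and would need replicates or a spike-in.

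The second pattern is the set of 582 SCR-only peaks with at most 3 KDMEIS2 tags. Reads placed independently at random are argued against, because the false discovery rate of the SCR call allows about 7.30 such peaks and there were 582. Uneven pile-ups of background reads in the SCR library are a candidate explanation: with satellite and rRNA repeats left out, 6.01% (4.22 to 8.26%) lay within 20 kb of a shared peak, near the 4.35% of shuffled positions and below the 12.6% (10.5 to 15.0%) of weak shared peaks. The rule, written before this test was run, asked whether the upper bound lies below the midpoint of the last 2 values. That midpoint came out at 8.50%, so the margin is narrow, and the 20 kb window and the tag limits were chosen after seeing the data. A loss of AML1-ETO from some of these sites after MEIS2 knockdown was not tested and stays open.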
